A study of Mus musculus with 11 samples.

How the data were processed

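RNA was sequenced from whole liver, per the labels, of 11 male Clec4f-DTR mice: 3 on chow, 4 on western diet with alcohol with serial saline injections and 4 on that diet with serial DT injections. The labels name poly(A) RNA and, in the extraction text, a preparation of CD45-positive cells for single-cell work. That text was read as belonging to another part of the study because the sample labels name whole liver tissue and hepatocyte transcripts such as Alb were abundant. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR to GRCm39 and counted per gene with featureCounts. Versions, annotation release, strand setting and the treatment of read mates are not stated. The deposited values are raw counts per Ensembl gene from the authors, 1 column per library, for 55414 genes. Low counts were mostly even in all 11 libraries, which is what counting both mates of a pair would give, so the number of independent fragments may be about 1 for each 2 counts, and halved counts were tried. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

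Totals ran from 43995217 to 58089531 counts per library. A count of 3 corresponds to 0.0398 to 0.0773 CPM, which is taken as the lower limit of detection and covers counting error only. Genes were kept with edgeR's filterByExpr at default settings, which left 17038 of the 28842 genes with any count. Factors were TMM. The fit was edgeR's quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with 1 mean per group over the 3 groups together, robust estimates, 8 residual degrees of freedom and a common biological coefficient of variation of 30.1%. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison at 0.05. The p-values set a difference between groups against the spread between these livers, estimated over the 3 groups together. The DT livers thus also enter the spread used for saline against chow. Log2 CPM used a prior count of 2.

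The 35 lists of cell types, pathways and checks were tested with limma's camera at a preset correlation of 0.01, with at least 5 members tested and adjustment over lists, and again with an estimated correlation and with fry. The lists held 450 entries for 446 genes, and 4 genes were in more than 1 list. Symbols came from a mouse annotation of an earlier build than the authors' alignment, matched by Ensembl identifier. GC content was known for 99.7% of tested genes. No coordinates are given.

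Genes named in the text were taken by a rule fixed in advance. It names 15 fixed genes in every comparison. It adds the 5 largest rises and the 5 largest falls among called genes with a mean log2 CPM of at least 2, an official symbol and no overlap between the 2 groups. It then adds up to 4 members with the smallest p of each list described, and genes that marked a library. Not every gene so taken is reported here. Members beyond these are named where 5 or fewer of a list went 1 way, and those were chosen after their values were seen. An early version of this step used edgeR's average log2 CPM, and it was replaced by the mean that the rule states after the first picks had been seen.

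The calling of genes was tested on simulated counts with 200 genes changed. For saline against chow, 42% of genes changed 2-fold and 73% of those changed 4-fold were recovered among 16488 genes, with 8 false calls. For DT against saline these were 44% and 72% among 16463 genes, with 6 false calls, and for DT against chow 36% and 66% among 16438 genes, with 5 false calls. Counts of calls are thus incomplete at these group sizes. No 2 libraries of a group were copies of each other.

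Alternatives set in advance were RLE factors, DESeq2 1.42.0, limma-voom with and without sample weights, no filter, a filter of 1 CPM in 3 libraries, only the compared groups in the fit, the replicate number as a block, a minimum log2 fold change of 1, and each library left out. After the data were seen, correction for GC content (loess, span 0.3), halved counts, upper quartile and total count scaling, and leaving out DT livers 1 and 2 together were added. Other splits of the livers into groups of the same sizes were counted, 35 for each comparison. The effect of DT on diet genes used the 6 choices of 2 saline livers and 8 simulations, and its spread is the SD over the 4 DT livers. That spread replaced the SD over the choices of saline livers after the values were seen, which made 2 of the refits without 1 liver count as moved. The overlap used 20 simulations. No library was left out of the fits reported. Western diet without alcohol, which the treatment text mentions, was not analysed here.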

Results

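RNA was measured by sequencing in whole livers of 11 male Clec4f-DTR mice, which carry a diphtheria toxin (DT) receptor under the promoter of Clec4f, a gene of resident liver macrophages (Kupffer cells). Mice entered the diets at 8 weeks of age and stayed on them for 16 weeks. The livers fell into 3 groups: 3 from mice on chow, 4 from mice on western diet with alcohol given serial saline injections (saline livers), and 4 from mice on the same diet given serial DT injections (DT livers). The counts per liver summed to between 43995217 and 58089531, and 17038 genes were tested. Values are TMM-normalised CPM as mean ± SD between livers of a group, and log2 fold changes (log2 FC) come from edgeR's quasi-likelihood test. A gene is said to have risen, fallen or changed, and is called, when its Benjamini-Hochberg adjusted p in that test was below 0.05, unless another tool is named. The comparisons, their tests, the 35 gene lists and the wording of the rule for naming genes were fixed before the data were examined, and what was added or changed later is stated where it is used. Which lists are described was chosen after their values were seen. Where a call ended in several refits that each left out 1 library, the refit with the highest adjusted p is named. A call said to have ended in 1 refit may thus have ended in others too.

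Clec4f, whose promoter drives the receptor, was at 47.5, 50.3 and 37.1 CPM in chow livers 1 to 3 and at 46.6, 49.1, 43.1 and 44.9 CPM in saline livers 1 to 4. In DT livers 1 to 4 it was at 9.06, 15.2, 7.51 and 6.18 CPM, below each of the other 7 livers. The first principal component of the 500 most variable genes held 75.9% of their variance and set DT livers 1, 3 and 4 apart from the other 8. DT liver 2 lay near the saline livers on it. The second component held 11.3% and separated chow from saline livers.

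**Figure D1:**
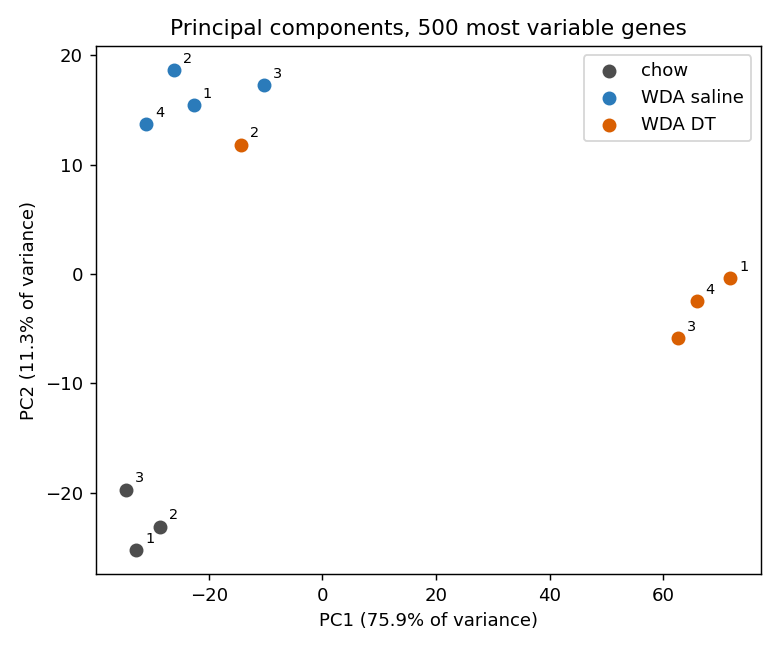
Principal components of log2 CPM of the 500 genes with the largest variance, with each point a liver labelled by its replicate number. PC1 (75.9% of variance) sets DT livers 1, 3 and 4 apart, and DT liver 2 lies near the saline livers.

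The comparison of saline with chow livers asked what western diet with alcohol changed while Kupffer cells were left in place. The titles of the chow samples name no injections. If chow mice had none, effects of serial injection cannot be separated from those of the diet in comparisons with chow livers. Of the lipogenesis and lipid storage lists 10 genes rose, among them Scd1, Srebf1, Pparg and Cd36, and 2 fell. Genes of cholesterol synthesis fell, among them Sqle, Cyp51 and Srebf2, as did the fatty acid hydroxylase gene Cyp4a14. Interferon-response genes such as Ifit3 and Isg15 rose. No Kupffer cell marker of the list changed by edgeR's test over all 3 groups, though Cd163 was called lower in some refits. In all 950 genes changed, 417 higher and 533 lower, and 488 of them by at least 1 log2 unit.

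Scd1 rose from 1944 ± 453 CPM (SD, n = 3) to 30434 ± 5028 CPM (SD, n = 4), a log2 FC of 3.97 (SE 0.32, adjusted p = 0.000137). Its relative Scd3 rose by 4.57 (SE 0.22, adjusted p = 2.18e-06), and reads shared between the Scd genes could not be separated. Of the 12 lipogenesis genes, 5 rose (Scd1, Srebf1, Acaca, Elovl6 and Acly), none fell and 7 were not called, against 7 called when adjusted over the list alone (6 higher and 1 lower). The camera adjusted p of that list was 1.26e-07, and 0.149 with an estimated correlation. Srebf1 rose by 3.09 (adjusted p = 0.00381), while Fasn was not called (log2 FC 1.15, adjusted p = 0.233). The Acaca and Elovl6 calls ended without chow replicate 1 (adjusted p = 0.058 and 0.123). Of the 12 lipid storage genes, 5 rose (Pparg, Cd36, Mogat1, Cidec and Cidea), 2 fell (Plin5 and Pnpla2) and 5 were not called, and 9 were called when adjusted over the list alone. Pparg rose by 1.93, Cd36 by 1.87 and Mogat1 by 3.71, while Plin5 fell by 1.45 (adjusted p = 0.000125, 0.001, 0.00291 and 0.00628). The list had a camera adjusted p of 1.64e-06, and 0.0511 with an estimated correlation. Of the 16 cholesterol synthesis genes, 6 fell, none rose and 10 were not called, and 10 were called when adjusted over the list alone (camera adjusted p = 8.3e-11, and 0.149 with an estimated correlation). Sqle fell by 5.77, Idi1 by 2.74, Cyp51 by 2.00 and Srebf2 by 1.00 (adjusted p = 0.00413, 0.00656, 0.00133 and 0.00171).

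Of the 16 fatty acid oxidation genes, 2 rose (Ppara and Vnn1), 3 fell (Cyp4a14, Ehhadh and Pdk4) and 11 were not called, and 11 were called when adjusted over the list alone. The list's camera adjusted p was 0.00057, and 0.344 with an estimated correlation, towards lower values. Cyp4a14 fell by 3.28 (SE 0.47, adjusted p = 0.0038). The Ppara, Ehhadh and Pdk4 calls ended when 1 library was left out, with adjusted p of 0.104 without chow replicate 2 for Ppara and of 0.101 and 0.204 without chow replicate 1 for Ehhadh and Pdk4. Of the 11 such refits, 6, 7 and 2 kept the calls of Ppara, Ehhadh and Pdk4. Of the 14 interferon-response genes, 6 rose, none fell and 8 were not called, and 11 were called when adjusted over the list alone (camera adjusted p = 8.3e-11, and 0.149 with an estimated correlation). Ifit3 rose by 1.51 and Isg15 by 1.40 (adjusted p = 0.00618 and 0.00667). Of the 9 MHC class II genes, 6 rose, none fell and 3 were not called, and 7 were called when adjusted over the list alone (camera adjusted p = 1.26e-07, and 0.342 with an estimated correlation). H2-Eb1 rose by 1.84 (adjusted p = 0.0211), a call that ended without chow replicate 1 (adjusted p = 0.11). Of the 14 acute-phase genes, 1 rose (Steap4), 6 fell and 7 were not called, and 7 were called when adjusted over the list alone (camera adjusted p = 0.000815, and 0.344 with an estimated correlation). Saa1 and Saa2 fell by 4.13 and 4.73, from chow livers that differed widely among themselves (1470 ± 1158 CPM for Saa1). The calls of Saa1, Saa2, Orm2 and Steap4 ended without chow replicate 2 (adjusted p = 0.0698, 0.0738, 0.0852 and 0.0887) and that of Saa3 without chow replicate 1 (adjusted p = 0.0621). The Saa2 call was kept in 5 of the 11 refits without 1 library. Saa1 and Saa2 are near-identical, so their separate values are uncertain.

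Of the 12 Kupffer cell markers, none rose or fell by edgeR's test and 12 were not called, and 0 were called when adjusted over the list alone. At an unadjusted p below 0.05 there were 3 of them, DESeq2 called 0 and limma-voom called 1. That gene was Cd163, at 49.7 ± 8.55 CPM in chow and 15.7 ± 4.56 CPM in saline livers (log2 FC -1.66, adjusted p = 0.17 by edgeR), and edgeR called it without DT replicate 2 (adjusted p = 0.00825). With only the compared groups in the fit edgeR called 2 markers, Cd163 lower and Il18bp higher (-1.64 and 0.54, adjusted p = 0.00404 and 0.0321), and without DT replicates 1 and 2 together it called them too (adjusted p = 0.00123 and 0.0324). Their median log2 FC was 0.10 and their mean -0.01, and the camera adjusted p was 0.636 (0.952 with an estimated correlation). Clec4f (0.03), Vsig4 (-0.06), Timd4 (-0.17), Cd5l (0.50) and Marco (0.45) were not called, and neither were Adgre1, Csf1r, Trem2, Gpnmb, Ccr2, Col1a1, Timp1, Cyp7a1 or Alb. DESeq2 called Gpnmb (3.68, adjusted p = 0.00393) and Ccr2 (2.02, adjusted p = 0.00404), and edgeR with only the compared groups in the fit called Ccr2 and Col1a1 (adjusted p = 0.00774 and 0.0468). Without saline replicate 4 edgeR called Gpnmb, and without DT replicate 2 it called Col1a1 (adjusted p = 0.0318 and 0.0446). As lists, the fibrosis genes (none called) and lipid-associated macrophage genes (2 rose) were higher by camera (adjusted p = 0.000187 and 7e-05). With an estimated correlation these were 0.522 and 0.344. DESeq2 called 4 fibrosis and 6 lipid-associated macrophage genes, and limma-voom called 0 and 2. By edgeR 6 genes of each of these lists had an unadjusted p below 0.05. Fibrosis scores (mean log2 CPM of the list minus that of chow) were 0.50 to 1.86 in saline and -0.27 to 0.33 in chow livers. Of the 12 circadian genes, 3 rose (Dbp, Nr1d2 and Per2), 2 fell (Arntl and Cry1) and 7 were not called, and 6 were called when adjusted over the list alone (camera adjusted p = 0.174, and 0.344 with an estimated correlation). The calls of Dbp, Nr1d2, Arntl and Cry1 ended without chow replicate 1 (adjusted p = 0.177, 0.112, 0.118 and 0.162), and the labels give no hour of harvest. Of the 11 refits without 1 library, 3, 8, 6 and 4 kept the calls of Dbp, Nr1d2, Arntl and Cry1. The 5 largest rises under the naming rule were Cyp2b9 (6.42), Scd3, Mmp12 (4.53), Lepr (3.99) and Scd1. The 5 largest falls were Saa2, Saa1, Selenbp2 (-3.71), Cdkn1a (-3.61) and Cyp4a14. The Selenbp2 call held without any 1 library. The calls of Cyp2b9, Mmp12 and Lepr ended without chow replicate 1 (adjusted p = 0.125, 0.0898 and 0.168) and that of Cdkn1a without chow replicate 3 (adjusted p = 0.0891). The Lepr call was kept in 4 of the 11 refits without 1 library. Reads of Cyp2b9 and its relatives could not be separated, and Mmp12 and Cdkn1a overlap genes on the other strand.

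By limma-voom fewer genes were called than by edgeR in 6 of the lists described: 4 interferon-response, 6 lipid storage, 3 MHC class II, 3 fatty acid oxidation, 3 acute-phase and 1 circadian gene. It called more in the cholesterol synthesis (7) and Kupffer cell (1) lists. Of the 39 genes taken by the naming rule and called in this comparison, 16 stayed called in each of the 11 refits without 1 library. The count of 950 was 287, 309 and 491 without chow replicates 1, 2 and 3, was 608, 429, 508 and 632 without saline replicates 1 to 4, and was 1454 and 1924 without DT replicates 1 and 2, while under total count scaling 67.0% of called genes were higher against 43.9% and the median log2 FC shifted by 0.13.

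The comparison of DT with saline livers asked what removal of Clec4f-positive cells changed on the same diet. All mice carried the receptor, so other effects of DT could not be separated from the loss of these cells. Kupffer cell markers fell, with Timd4 and Cd163 nearly lost and Clec4f and Vsig4 reduced. Genes of fibrosis (Col1a1, Acta2), of bile ducts and ductular reaction (Krt19, Sox9, Epcam) and of the cell cycle (Ccnb2, Cdk1) rose. Genes of the lipid-associated macrophage list, such as Trem2 and Spp1, rose as well, though whole liver RNA cannot tell which cells expressed them. Ppara fell. By list scores these rises rested on DT livers 1, 3 and 4, while DT liver 2 was not above the saline livers. Single genes differed from this, and Acta2 was at 9.90 CPM in DT liver 2, above DT livers 3 and 4 (5.34 and 2.31 CPM) and the saline livers (0.611 to 1.54 CPM). In all 3734 genes changed, 2436 higher and 1298 lower, and 1992 of them by at least 1 log2 unit.

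Clec4f fell from 45.9 ± 2.55 CPM (SD, n = 4) to 9.48 ± 3.98 CPM (SD, n = 4), a log2 FC of -2.28 (SE 0.24, adjusted p = 0.00125). Of the 12 Kupffer cell markers, none rose, 10 fell and 2 were not called, and 11 were called when adjusted over the list alone (camera adjusted p = 1.31e-14, and 0.259 with an estimated correlation). Timd4 fell by 4.44, Cd163 by 5.59, Marco by 2.84 and Vsig4 by 1.61 (adjusted p = 0.00125, 0.00396, 0.00626 and 0.000871). Cd163 was at 0, 1.25, 0.113 and 0.106 CPM in DT livers 1 to 4, and its log2 FC ranged from -7.67 to -5.16 over refits without 1 library. Cd5l fell by 0.63 (adjusted p = 0.0298), a call that ended without DT replicate 4 (adjusted p = 0.0875) and under total count scaling (-0.32, adjusted p = 0.153). Adgre1 fell by 0.60 (adjusted p = 0.0304), a call that ended without saline replicate 2 (adjusted p = 0.0786) and under total count scaling (-0.24, adjusted p = 0.413), upper quartile scaling, the GC correction and the replicate block (adjusted p = 0.0613, 0.0688 and 0.0512). Csf1r was not called (-0.34, adjusted p = 0.164). Of the 12 general macrophage genes, 2 rose, 1 fell (Adgre1) and 9 were not called, with a median log2 FC of 0.22 (camera adjusted p = 0.543, and 0.864 with an estimated correlation). Of the 14 genes of lipid-associated macrophages, 8 rose, 1 fell (Lipa) and 5 were not called, and 10 were called when adjusted over the list alone (camera adjusted p = 0.00075, and 0.463 with an estimated correlation). Trem2 rose from 1.72 ± 1.24 to 11.2 ± 5.18 CPM (log2 FC 2.70, SE 0.51, adjusted p = 0.00774). Cd63 rose by 2.85 and Spp1 by 3.10 (adjusted p = 0.00877 and 0.0102). Gpnmb rose by 2.79 (adjusted p = 0.0395), a call kept in only 2 of the 11 refits without 1 library. Its highest adjusted p was 0.0955, without DT replicate 4. The fall of Lipa (-0.54, adjusted p = 0.0118) was not called after a correction for GC content (-0.14, adjusted p = 0.636) or under total count scaling (-0.21, adjusted p = 0.155). Ccr2 was not called (1.03, adjusted p = 0.15) except after the GC correction, without DT replicate 2 and without DT replicates 1 and 2 together (adjusted p = 0.0425, 0.0471 and 0.00383).

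Of the 16 fibrosis genes, 13 rose, none fell and 3 were not called, and 14 were called when adjusted over the list alone (camera adjusted p = 5.16e-09, and 0.463 with an estimated correlation). Col1a1 rose from 8.79 ± 4.17 to 63.1 ± 36 CPM (log2 FC 2.84, SE 0.53, adjusted p = 0.00766), and Acta2, Col6a3 and Mmp2 rose by 2.86, 3.08 and 3.32. Timp1 was not called (2.26, adjusted p = 0.106) except without DT replicate 2 (adjusted p = 0.0463). Of the 12 ductular genes, 10 rose, none fell and 2 were not called, and 10 were called when adjusted over the list alone (camera adjusted p = 0.000132, and 0.463 with an estimated correlation). Krt19 rose by 4.53, Epcam by 4.09, Muc1 by 3.66 and Sox9 by 2.96 (adjusted p = 0.00563, 0.00813, 0.00678 and 0.00577). DESeq2 called 10 ductular genes and limma-voom 3, without Krt19, Epcam and Muc1 (adjusted p = 0.053, 0.109 and 0.055). The ductular score of DT liver 2 was -0.16, below the -0.08 to 0.70 of the saline livers, so the rise rested on DT livers 1, 3 and 4 (2.86 to 3.65). Of the 14 proliferation genes, 8 rose, none fell and 6 were not called, and 9 were called when adjusted over the list alone (camera adjusted p = 0.000558, and 0.463 with an estimated correlation). Ccnb2 rose by 2.95 and Cdk1 by 2.34 (adjusted p = 0.00802 and 0.0119). Of the 12 p53 target genes, 6 rose, 1 fell (Fas) and 5 were not called, and 8 were called when adjusted over the list alone (camera adjusted p = 0.0353, and 0.463 with an estimated correlation). That list was not called without saline replicates 1 or 4 or without DT replicate 1 (adjusted p = 0.0611, 0.0819 and 0.0656). Cdkn1a rose by 4.14 and Phlda3 by 2.31 (adjusted p = 0.00813 and 0.011). Cdkn1a was at 1.68 to 9.75 CPM in saline, 22.0 to 144 CPM in DT and 21.9 to 86.7 CPM in chow livers. Its rise thus brought it back within or above the chow range. In list score DT liver 2 lay within the saline livers for fibrosis (1.57 within 0.50 to 1.86), proliferation (0.53 within 0.23 to 0.96), lipid-associated macrophages (1.54 within 0.48 to 1.87) and p53 targets (0.16 within -0.39 to 0.42). DT livers 1, 3 and 4 lay above them (3.52 to 3.76, 2.30 to 2.58, 2.71 to 3.09 and 0.98 to 1.31).

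Of the 16 fatty acid oxidation genes, 1 rose (Pdk4), 7 fell and 8 were not called, and 13 were called when adjusted over the list alone (camera adjusted p = 1.12e-05, and 0.463 with an estimated correlation). Ppara fell by 1.61 and Vnn1 by 1.42 (adjusted p = 0.000871 and 0.00442). The Pdk4 call ended without DT replicate 4 (adjusted p = 0.0719). Of the 12 endothelial genes, none rose, 4 fell (Kdr, Oit3, Tek and Stab2) and 8 were not called, and 8 were called when adjusted over the list alone (camera adjusted p = 0.00164, and 0.318 with an estimated correlation). Kdr fell by 0.55 and Oit3 by 0.49 (adjusted p = 0.0103 and 0.0126). None of these 4 endothelial genes was called under total count scaling, and the calls of Tek and Stab2 ended without DT replicates 4 and 3 (adjusted p = 0.0886 and 0.124). Of the 11 refits without 1 library, 6 kept the Tek call and 2 the Stab2 call. Of the 12 male-biased genes, none rose, 2 fell (Nudt7 and Cyp7b1) and 10 were not called, and 2 were called when adjusted over the list alone (camera adjusted p = 0.000333, and 0.463 with an estimated correlation). The Cyp7b1 call ended without saline replicate 4 (adjusted p = 0.0789). The male-biased score of DT liver 2 (-0.83) lay within the saline livers (-1.37 to -0.47), unlike those of DT livers 1, 3 and 4 (-5.93 to -4.01). Of the 12 circadian genes, 3 rose (Arntl, Npas2 and Cry1), 4 fell (Dbp, Per3, Nr1d2 and Tef) and 5 were not called, and 7 were called when adjusted over the list alone (camera adjusted p = 0.2, and 0.463 with an estimated correlation). Arntl rose by 2.27 and Nr1d2 fell by 1.07 (adjusted p = 0.0121 and 0.00699). The Tef call ended without saline replicate 4 (adjusted p = 0.06). Of the 10 mitochondrial transcripts, none rose or fell by edgeR's test, 10 were not called and 0 were called when adjusted over the list alone, although 4 had an unadjusted p below 0.05. The list's camera adjusted p was 0.000761 (0.463 with an estimated correlation), towards lower values, with DT liver 2 (score -0.03) within the saline livers (-0.15 to 0.10). DESeq2 called 3 of them (mt-Co1, mt-Co3 and mt-Nd5) and limma-voom 1 (mt-Co3). The 4 with the smallest p (mt-Co1, mt-Co2, mt-Co3 and mt-Nd5) were called lower by edgeR without DT replicate 2 (adjusted p = 0.00368, 0.0253, 0.00938 and 0.0306), and some of them without DT replicate 1, with the replicate block or after the GC correction. The scores of DT livers 1, 3 and 4 were -2.94, -0.95 and -0.78. The 5 largest rises under the naming rule were Lamc3 (4.79), Cdkn1a, Cyp2b10 (3.97), Dpt (3.51) and Adamtsl2 (3.45), and the 5 largest falls were Cd163, Marco, Car3 (-2.29), Clec4f and Nudt7 (-2.27). By limma-voom Lamc3, Mmp2 and Phlda3 were not called (adjusted p = 0.0696, 0.0502 and 0.0513). The Car3 call was kept in 5 of the 11 refits without 1 library and had its highest adjusted p (0.0956) without DT replicate 4. Car3 was at 1990 CPM in DT liver 2 and at 211 to 369 CPM in the other DT livers, and its log2 FC ranged from -3.67 to -1.99 over refits without 1 library. Alb, Fasn and Cyp7a1 were not called, although Cyp7a1 was called by DESeq2 (-1.44, adjusted p = 0.0156) and by edgeR without saline replicate 3 (-1.76, adjusted p = 0.0257). Lamc3, Cdkn1a, Arntl and Csf1r overlap genes on the other strand, and reads of Cyp2b10 and its relatives, or of mitochondrial genes and their nuclear copies, could not be separated.

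By limma-voom fewer genes were called than by edgeR in the fibrosis (9), ductular (3), proliferation (5) and p53 target (5) lists, and more in the male-biased (5), endothelial (6), fatty acid oxidation (9) and mitochondrial (1) lists. Of the 47 genes taken by the naming rule and called in this comparison, 37 stayed called in each of the 11 refits without 1 library. The count of 3734 was 2308, 1786 and 1869 without saline replicates 1, 2 and 4. It was 6824, 1879 and 1809 without DT replicates 2, 3 and 4. Of the called genes 65.2% were higher, against 75.7% under upper quartile scaling and 92.1% under total count scaling. Total count scaling shifted the median log2 FC by 0.34. The share of higher genes was 53.1% by limma-voom, 56.1% without DT replicate 2 and 52.9% without DT replicates 1 and 2 together.

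**Figure D2:**
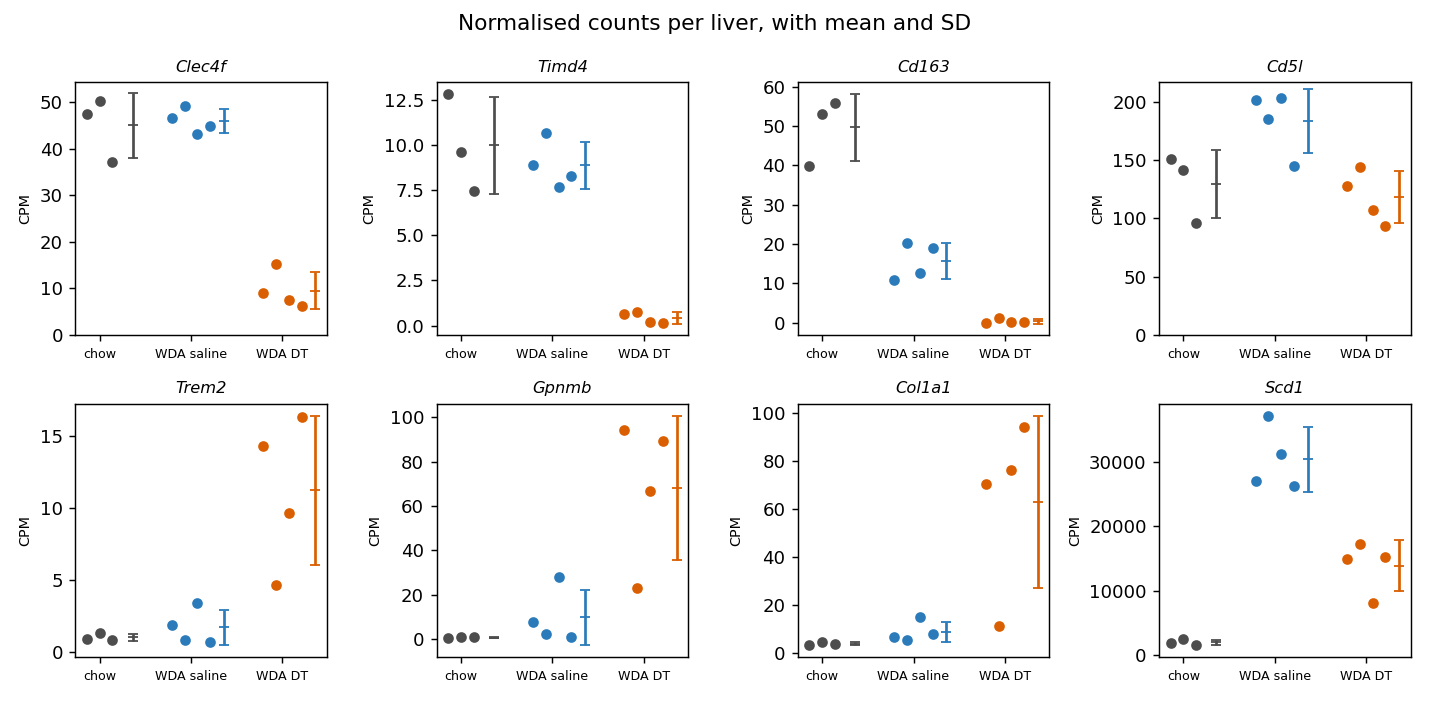
Normalised counts (CPM) of 8 genes in each liver, with points for livers and bars for the mean and SD of each group. Clec4f lay between 6.18 and 15.2 CPM in the DT livers and between 37.1 and 50.3 CPM in the other livers.

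**Figure D3:**
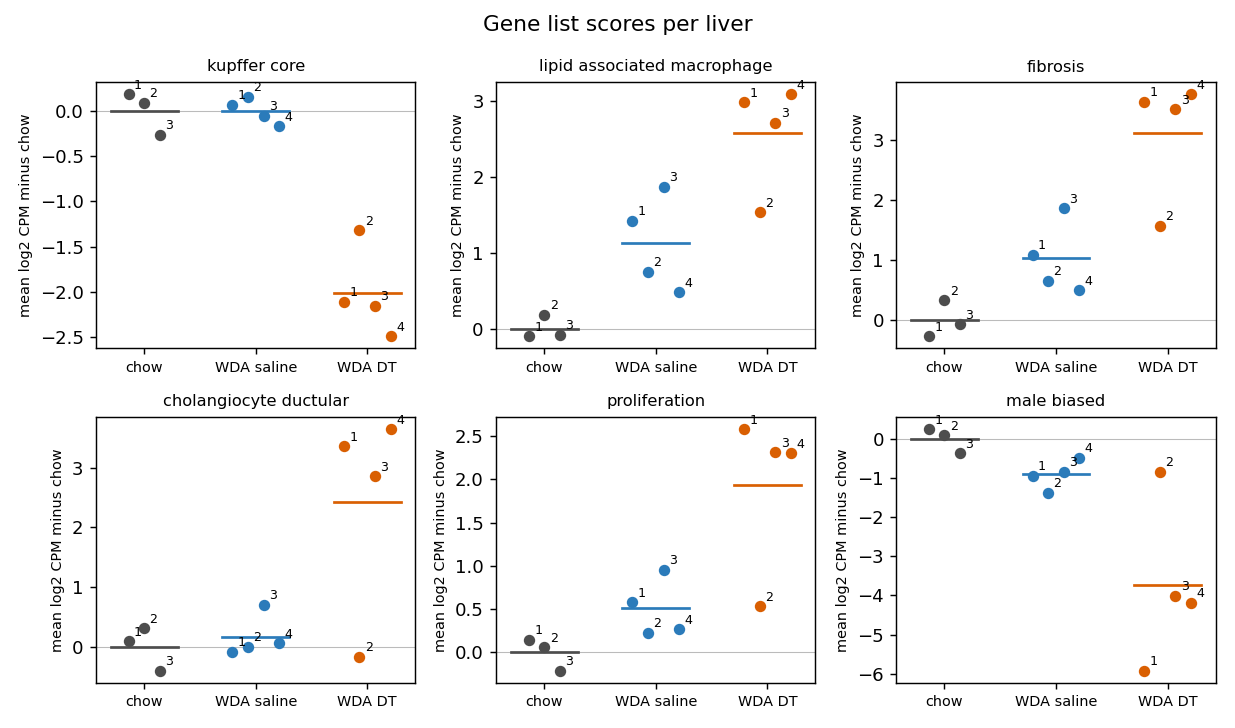
Scores of 6 gene lists per liver, each the mean log2 CPM of the list's genes minus the mean of the chow livers, with lines for group means and digits for replicate numbers. DT liver 2 had a fibrosis score of 1.57, and the other DT livers had scores of 3.52 to 3.76.

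The comparison of DT with chow livers took the diet and the toxin together, and with no chow-fed mice given DT the 2 could not be separated. Every fibrosis gene of the list rose, Col1a1 and Acta2 among them. Genes of the lipid-associated macrophage (Gpnmb, Itgax, Cd63) and monocyte (Cx3cr1, Ccr2) lists rose, while the Kupffer cell markers Clec4f, Timd4 and Cd163 fell. Genes of fatty acid oxidation and cholesterol synthesis fell, and MHC class II genes rose. In all 3919 genes changed, 2528 higher and 1391 lower, and 2382 of them by at least 1 log2 unit.

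Of the 16 fibrosis genes, 16 rose, none fell and 0 were not called, and 16 were called when adjusted over the list alone (camera adjusted p = 9.26e-14, and 0.163 with an estimated correlation). Col1a1 rose from 3.91 ± 0.74 CPM (SD, n = 3) to 63.1 ± 36 CPM (SD, n = 4), a log2 FC of 4.01 (SE 0.64, adjusted p = 0.00361), and Acta2 rose by 4.40. The Timp1 call (3.95, adjusted p = 0.0386) ended without chow replicate 3 (adjusted p = 0.125) and was kept in 4 of the 11 refits without 1 library. Of the 14 genes of lipid-associated macrophages, 11 rose, none fell and 3 were not called, and 11 were called when adjusted over the list alone (camera adjusted p = 4.48e-09, and 0.163 with an estimated correlation). Gpnmb rose by 6.44, Itgax by 4.29, Cd63 by 4.21 and Trem2 by 3.43 (adjusted p = 0.00605, 0.00467, 0.00408 and 0.00479). Of the 11 monocyte genes tested, 7 rose, none fell and 4 were not called, and 9 were called when adjusted over the list alone (camera adjusted p = 6.52e-06, and 0.187 with an estimated correlation). Cx3cr1 rose by 6.13, Ccr2 by 3.03 and Plac8 by 1.79 (adjusted p = 0.00209, 0.00733 and 0.00389), and limma-voom did not call Cx3cr1 (adjusted p = 0.0521). Of the 12 Kupffer cell markers, none rose, 10 fell and 2 were not called, and 11 were called when adjusted over the list alone, 10 lower and 1 higher (camera adjusted p = 1.34e-10, and 0.163 with an estimated correlation). Clec4f fell by 2.25, Vsig4 by 1.67, Timd4 by 4.61 and Marco by 2.38 (adjusted p = 0.000903, 0.000549, 0.000903 and 0.00857). Cd5l, Adgre1 and Csf1r were not called (-0.13, -0.25 and -0.33).

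Of the 12 ductular genes, 8 rose, none fell and 4 were not called, and 8 were called when adjusted over the list alone (camera adjusted p = 0.000212, and 0.287 with an estimated correlation). Krt19 rose by 4.07 and Krt7 by 4.63 (adjusted p = 0.00711 and 0.00802). DESeq2 called 8 ductular genes, but limma-voom called 0, with 3 at an unadjusted p below 0.05 (adjusted p = 0.0937 for Krt19 and 0.0554 for Krt7). The ductular score of DT liver 2 also lay within the chow livers (-0.40 to 0.31). Of the 16 cholesterol synthesis genes, none rose, 11 fell and 5 were not called, and 13 were called when adjusted over the list alone (camera adjusted p = 2.15e-09, and 0.163 with an estimated correlation). Cyp51 fell by 2.26 and Hmgcs1 by 1.16 (adjusted p = 0.000903 and 0.00615). Of the 16 fatty acid oxidation genes, none rose, 13 fell and 3 were not called, and 14 were called when adjusted over the list alone (camera adjusted p = 7.18e-12, and 0.163 with an estimated correlation). Cyp4a14 fell by 3.20 and Ehhadh by 1.75 (adjusted p = 0.00322 and 0.00353). Hadhb fell by 0.98 (adjusted p = 0.00403) and was not called after a correction for GC content (-0.44, adjusted p = 0.387). Of the 9 MHC class II genes, 8 rose, none fell and 1 was not called, and 8 were called when adjusted over the list alone (camera adjusted p = 1.46e-09, and 0.163 with an estimated correlation). H2-Eb1 rose by 2.68 and Ciita by 2.44 (adjusted p = 0.00353 and 0.00322). Of the 12 male-biased genes, none rose, 6 fell and 6 were not called, and 9 were called when adjusted over the list alone (camera adjusted p = 9.55e-08, and 0.187 with an estimated correlation). The score of DT liver 2 (-0.83) lay below the chow livers (-0.35 to 0.26) but far above DT livers 1, 3 and 4 (-5.93 to -4.01). Selenbp2 fell by 3.30 and Serpina1e by 3.05 (adjusted p = 0.00661 and 0.0138). The 5 largest rises under the naming rule were Gpnmb, Cyp2b9 (5.58), Mmp12 (5.36), Ly6d (5.26) and Gstm3 (4.67), and the 5 largest falls were Cd163 (-7.25), Selenbp2, Susd4 (-3.23), Cyp4a14 and Serpina1e. The Cyp2b9 call ended without chow replicate 1 (adjusted p = 0.0715) and the Susd4 call without DT replicate 3 (adjusted p = 0.0701). Fasn rose by 1.67 (adjusted p = 0.0421), a call that ended without chow replicate 2 (adjusted p = 0.129), and Alb and Cyp7a1 were not called. The Fasn call was kept in 3 of the 11 refits without 1 library. Without DT replicates 1 and 2 together edgeR called Alb lower (-0.56, adjusted p = 0.0145). Reads of Serpina1e, Gstm3, Cyp2b9 and Cyp4a14 and their relatives could not be separated.

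By limma-voom fewer genes were called than by edgeR in the fibrosis (10), ductular (0), lipid-associated macrophage (10), monocyte (6) and cholesterol synthesis (10) lists, and more in the male-biased list (9). Of the 46 genes taken by the naming rule and called in this comparison, 40 stayed called in each of the 11 refits without 1 library. The count of 3919 was 1786, 1870 and 1870 without chow replicates 1, 2 and 3 and was 6834, 2458 and 2223 without DT replicates 2, 3 and 4, while 64.5% of called genes were higher, against 77.6% under upper quartile scaling (median shift 0.11) and 94.8% under total count scaling (median shift 0.47). That share was 50.6% by limma-voom, 52.1% by limma-voom with sample weights and 52.2% without DT replicates 1 and 2 together.

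Of the 35 lists, camera called 16 in saline against chow, 17 in DT against saline and 26 in DT against chow, and with an estimated correlation it called 0, 0 and 0 (6, 3 and 10 at an unadjusted p below 0.05). The tests of fry, which ask whether a list's genes move 1 way on balance, called 7, 4 and 26.

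Whether DT moved the diet's genes further from chow or back towards it was asked with separate saline livers for each contrast. Among genes that changed on the diet with 2 of the saline livers, the median log2 change from the other 2 saline livers to the DT livers, signed by the diet's change, was -0.40 on average over the 6 choices (-0.54 to -0.21), and 78.0% of the genes moved opposite to the diet. An average of 270 genes entered. The value was negative in each DT liver, at -0.41, -0.36, -0.48 and -0.38 in livers 1 to 4. DT livers simulated without any effect of the toxin gave -0.00, with 47.6% to 51.0% of genes moving opposite over 8 simulations. Genes were drawn independently of each other there, and an average of 875 genes entered. Variation shared between genes, which would widen that range, was not included, so the range does not measure how far chance could move the value. With the same 4 saline livers in both contrasts the value was -0.39, against -0.11 in the simulation. No p-value was computed for it. Any difference particular to the saline livers, such as one of harvest time, would also give a negative value. Choosing separate saline livers cannot remove it. In log2 Dbp minus log2 Arntl the saline livers (4.30 to 6.37) lay above both the chow (-1.46 to 2.18) and the DT livers (-2.91 to 2.81). Such a difference and a return caused by DT therefore cannot be told apart here.

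The changes of saline and DT livers against chow were compared gene by gene. They shared 484 called genes, of which 255 rose in both, 220 fell in both and 9 went opposite ways. Independent lists of the same sizes would share 61.9 rising and 43.5 falling genes. The log2 fold changes had a covariance of 0.576 across genes, against 0.148 in 20 simulations of groups without any effect against the same chow livers, and a correlation of 0.55 against 0.61. Part of the overlap may come from the shared chow livers, which were too few to split, and genes are not independent replicates. The 20 simulations also drew genes independently of each other. The 475 genes called the same way were 135 without chow replicate 1, 145 and 225 without chow replicates 2 and 3, 291, 243 and 268 without saline replicates 1, 2 and 3, and 991 without DT replicate 2.

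DT liver 1 differed from the other livers in its AT-rich transcripts. Its autosomal genes below 40% GC had a median log2 deviation 1.07 lower than its genes above 50% GC, while in the other 10 livers this difference lay between -0.12 and 0.18. Mitochondrial transcripts made up 1.33% of its counts, against 4.82% to 7.53% in the others.

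**Figure D4:**
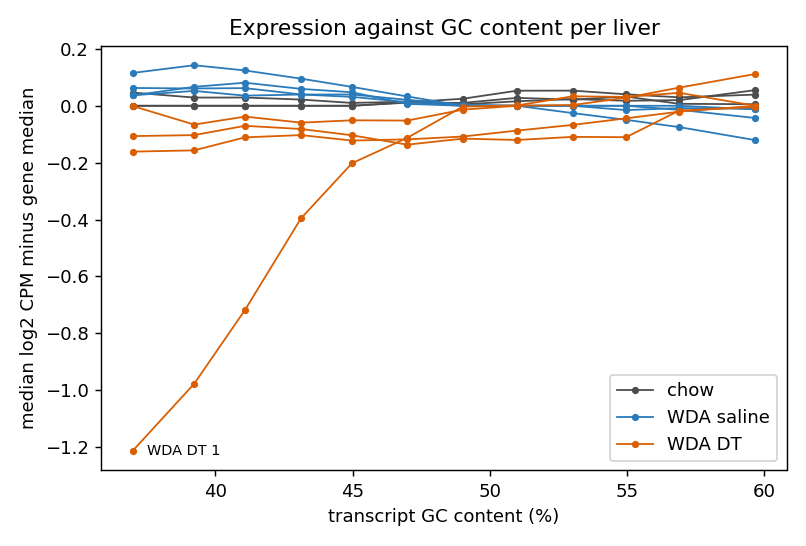
Median log2 CPM of genes relative to each gene's median over the livers, by GC content of the transcript, with a line per liver. The line of DT liver 1 falls at low GC content, and its difference between genes below 40% and above 50% GC was -1.07.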

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

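The counts over other splits of the livers were planned, and all other tests in this part were chosen after the result was seen. After values were known, the bounds of the test on Y-linked genes were changed, and the depth test was switched from Col1a1 to the fibrosis list. In groups of 4, a liver stood out when its gap to the nearest liver as a share of the group's range exceeded Dixon's 95% critical value. Of 82 such tests 9 passed, where chance alone gives about 1 in 20. The 9 are not independent, since the tests share livers and genes, and the lists tested were chosen after their values were seen.

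Every comparison was set against the other ways to split the same livers. For saline against chow, 1 of 35 splits gave as many called genes, the real one with 950, and the highest other gave 0. For DT against saline it was also 1 of 35, the real one with 3734, and the highest other gave 2751. For these 2 gene counts chance can be excluded at 0.05 only without adjustment for the number of counts tested. A share of 1 in 35 is the smallest that this test can reach. For DT against chow, 2 of 35 splits reached 3919, and the other one gave 6618. That split put DT liver 2 with the chow livers, which points to a structure of the samples in which DT liver 2 lies apart from the other DT livers, so chance cannot be excluded for that count. List calls did not stand out in any comparison. For saline against chow, 9 of 35 splits called at least the real 16 lists (highest other 19). For DT against saline 14 of 35 called at least 17 (highest other 24), and for DT against chow 3 of 35 called at least 26 (highest other 28).

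DT liver 2 stood out from the other DT livers in 3 values, which are not separate because Col1a1 is a member of the fibrosis list. Its fibrosis score was 1.57 against 3.52 for the nearest, its proliferation score 0.53 against 2.30, and its Col1a1 level 3.48 log2 CPM against 6.14. Its Kupffer cell score lay at -9.30 SD of the saline livers from their mean, which argues against a liver that had no toxin or a swapped label. The fibrosis genes had a median of 459.5 counts there, so low depth was excluded. A smaller loss of Kupffer cells may go with the smaller response, since its Kupffer score was 0.79 log2 above the highest of the other DT livers, a relation that rests on 1 liver and leaves cause and direction open.

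DT liver 1 stood out in its GC difference (-1.07 against -0.12 for the nearest) and in the Y-linked genes Ddx3y (2.28 against 5.47 log2 CPM), Uty (0.25 against 3.41) and Kdm5d (3.02 against 3.68). Xist had 0 counts there, which argues against a female or mixed sample. Among autosomal genes of like GC content, the 4 Y-linked genes tested lay at a median percentile of 17.5, low but not outside, so loss of AT-rich transcripts in that library and another cause cannot be told apart with 4 genes. A direct test of GC bias as the source of its low AT-rich transcripts would measure the pattern with itself and was left out. No biological explanation was tested.

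The last 2 values stood out alone. Saline liver 2 had a GC difference of 0.18 against 0.06, and saline liver 4 had Adgre1 at 4.64 log2 CPM, below the other saline livers. No explanation was tested for them.

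Clock genes differed between saline and DT livers. In log2 Dbp minus log2 Arntl, 0 of the 4 saline livers lay within the range of the DT livers (4.30 to 6.37 against -2.91 to 2.81). A different time of harvest might give this, and so might an effect of the toxin. They cannot be told apart because the labels give no hour, and the chow livers themselves ranged from -1.46 to 2.18.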

How the results depend on the processing

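The alternatives added after the data were seen were GC correction, halved counts, upper quartile and total count scaling, DT livers 1 and 2 left out together, and single livers left out for the overlap and, for chow and DT livers only, for the toxin's effect on diet genes. No gene taken by the naming rule and no described list reversed under an alternative where either fit called it. These list checks did not cover the fibrosis and lipid-associated macrophage lists in saline against chow. They also did not cover the general macrophage list in DT against saline. Some uncalled genes changed sign, such as Clec4f in saline against chow (-0.09 to 0.12 over refits without 1 library). The majority of lower genes in saline against chow (533 against 417 higher) turned. Higher and lower were 593 and 292 with total count scaling, 896 and 843 with DESeq2, 1660 and 1445 with only the compared groups, 1676 and 1635 without DT 1 and 2, 968 and 956 without DT 2, and 261 and 247 without saline 3. Of the comparisons of genes taken by the naming rule with an alternative, 3019 kept the call or its absence, 274 lost it and 45 gained it, and for described lists these were 452, 38 and 3. Called genes are given for saline against chow, DT against saline and DT against chow in that order, beside 950, 3734 and 3919. With an absolute log2 fold change of at least 1 they were 488, 1992 and 2382, by construction. Voom with sample weights gave 3700, 8618 and 8705, only the compared groups in the fit 3105, 2303 and 2089, and both DT 1 and 2 left out 3311, 7894 and 7827. DESeq2 gave 1739 for saline against chow, and total count scaling 5629 and 6536 for the DT comparisons. The replicate block gave 559 for saline against chow and 2210 for DT against chow. Correlations of same-numbered livers of different groups (-0.16 to 0.18) lay within those of other pairs (-0.26 to 0.22), so no pairing by number was seen. Leaving out 1 liver gave 287 (chow 1) to 1924 (DT 2), 1786 (saline 2) to 6824 (DT 2) and 1786 (chow 1) to 6834 (DT 2). DT liver 2 moved all 3 counts up when left out. Other alternatives kept each count within 1.5 times. The fit shares 1 estimate of the spread over the 3 groups, so the DT livers enter the spread used for saline against chow. That count was 1454, 1924, 828 and 849 without DT 1 to 4, although no DT liver is in that comparison. With only the compared groups it was 3105. Some of these fits also held fewer livers or genes, and no cause was tested.

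Of 35 lists, camera's 16, 17 and 26 calls became 0, 0 and 0 with an estimated correlation and 7 and 4 with fry for the first 2 comparisons (fry kept 26 for the last), and leaving out 1 liver gave 15 to 17, 12 to 20 and 23 to 27. The 475 genes called the same way against chow were 829 with DESeq2, and 135 (chow 1) to 991 (DT 2) with 1 liver left out. The toxin's effect on diet genes was -0.49 (chow 1) to -0.31 (DT 2) with 1 chow or DT liver left out, beside -0.40. No saline liver was left out for it, and the choices of saline livers gave -0.54 to -0.21. The cause was not tested. Depth limits genes near 0.0398 to 0.0773 CPM, the level of 3 counts.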

Other observations

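The tests in this part were all chosen after the data were seen, on 3 lists written then, and are values without an explanation. H19 was at 497, 0.29, 177 and 22.4 CPM in DT livers 1 to 4 and at 0.256 CPM or less in the other 7 livers. Of 10 genes of fetal or tumour liver, H19 included, 9 rose in DT against saline (unadjusted camera p = 3.91e-06, and 0.1 with an estimated correlation). Of 11 pericentral genes 3 fell (p = 0.000101, and 0.173 with an estimated correlation), and Cyp2e1 was at 3031, 9735, 1917 and 2032 CPM in DT livers 1 to 4 against 10276 to 13220 CPM in the saline livers. Of 11 periportal genes 5 rose (p = 0.00274, and 0.183 with an estimated correlation), Sds among them (log2 FC 1.67, adjusted p = 0.00544). The periportal list was lower in saline than in chow livers, with 3 genes that fell (p = 6.40e-07, and 0.0391 with an estimated correlation). Between DT and chow livers camera detected no shift of that list (median log2 FC -0.14, p = 0.298, and 0.622 with an estimated correlation), while 1 gene rose and 2 fell. The periportal score of DT liver 2 (-0.67) lay within the saline livers (-1.10 to -0.50).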
